A study of Triticum aestivum with 48 samples.

How the data were processed

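DNA affinity purification sequencing (DAP-seq) maps where a purified transcription factor binds naked genomic DNA in vitro. The factors were SPL proteins of bread wheat, a plant family that binds DNA through the SBP domain. Per the labels' protocols, each full-length SPL was made as a HALO-tagged fusion in a cell-free expression system from 500 ng of plasmid and held on magnetic beads. It was then offered 500 µg of sonicated genomic DNA of 200 to 800 bp for 1 h. The DNA came from leaves of 2-week-old seedlings of the cultivar AiKang58. After 8 washes the bound DNA was tagmented on the beads with Tn5 transposase and amplified for 10 to 13 cycles. The DNA was free of chromatin, so the lists describe binding in vitro and not occupancy in leaves.

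The series held 48 libraries, of which 46 were SPL libraries of 40 SPL proteins and 2 were input libraries. SPL1D, SPL2A, SPL6A, SPL8A, SPL9A and SPL19B had 2 libraries each, and the other 34 SPL proteins had 1 each. The values used here were the positions of peaks, as deposited by the authors in 1 list per SPL and 1 list for the input, with no score, height or summit. How libraries of the same SPL were combined is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.36, Bowtie2, MACS2 and bedtools, without roles. The genome build was not given in the sources used here. On 21 of the 21 chromosomes the last peak ended before the last gene of the wheat reference assembly RefSeq v2.1, so gene positions of that assembly were not used. Positions are given as in the deposited lists, counted from 1.

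The deposited lists showed traces of filtering when checked. Every SPL list had a narrowest peak of 201 bp, no peak outside the 21 chromosomes and no overlap with an input peak. The input list had 223198 peaks, the narrowest of 150 bp, and 15889 of them lay on unplaced sequence. Between 42.8% (SPL14B) and 98.2% (SPL8B) of the peaks of a list had a width that was a multiple of 25 bp. No source used here explains this range. Read depth per library is unknown, so no counting interval was given for any value.

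Lists were named by SPL number, which marks a set of homoeologs, and by the letter of the subgenome that encodes the protein. SPL8D1 and SPL18D2, whose names end in a further digit, were counted as the D homoeologs of SPL8 and SPL18. The 40 lists covered 17 numbers, of which 10 had 3 lists, 3 had 2 lists and 4 had 1 list. Similarity of a pair of lists was the Jaccard index. Peaks of both lists were merged where they shared 1 bp or more, and the merged regions with peaks of both lists were divided by all merged regions. Homoeologous pairs were compared with other pairs by permuting the numbers over the lists. Pairs with the same letter were compared with pairs of different letters by permuting the letters, with homoeologous pairs left out. Peak density was peaks per Mb of A, B or D chromosomes, with each chromosome's length taken from its last peak in any list. The log2 ratios of density were tested by flipping signs over the 40 lists, with Benjamini-Hochberg adjustment over the 3 ratios. Own-subgenome binding was a list's share of peaks on its own subgenome minus the mean share of its homoeologs there, tested by permuting letters within a number. All these tests were two-sided, with 100000 permutations unless another number is given, and 1e-05 is the smallest p they can give.

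Peaks of all 40 lists were merged into regions, and the lists with a peak in each region were counted. The background was 1 draw in which every peak was placed at random on its own chromosome. A second background shifted all peaks of a list by 1 distance drawn between 200000 and 1000000 bp, which keeps the local spacing of peaks. Peaks with no overlap in any other list are called private, and those that overlapped peaks of at least 20 other lists are called widely shared. The planned split of peaks by strength needed a score. Peak width took its place after the lists were seen, and width is not a measure of affinity. Motif, promoter, gene list and homoeologous gene analyses were not run, because no genome or annotation of the same build was used here.

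The SPL proteins named were the 3 with most and the 3 with fewest peaks, the extremes of each comparison, and the homoeolog sets with the highest and lowest similarity. The regions named were the 10 bound by most SPL proteins, with ties broken by the mean percentile of peak width within each list, in place of score. Names outside this rule were chosen after their values were seen, and these include the pairs of SPL8 with SPL13, SPL16 and the start of chromosome 1B. Designs, tests and the following alternatives were fixed before the data were examined: a reciprocal overlap of 50%, leaving out each SPL number or chromosome group, windows of 200 bp around peak centres for shared regions, and splits at 10% of peaks, planned by score. Others, such as the widest 50% of each list, were added after seeing the data.

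Each SPL had 1 list, so there were no replicates within an SPL, and every SD is over lists. The 40 lists share a DNA source and an input and are not independent. A sign-flip p therefore measures how uniform a difference was across these lists. A p from permuted numbers or letters measures how closely those labels went with the values of these lists. On simulated data without an effect, 5% of number tests, 6.5% of letter tests and 6% of own-subgenome tests passed 0.05 over 200 simulated sets. These sets were independent random values, without the differences in width between lists or the similarity of homoeologs. They do not show how the tests behave with such structure. With an SPL number effect planted in 40 simulated lists, the permutation p was 0.0001. The simulations used fewer permutations, and 0.0001 was the smallest p possible in that test. Computations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.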

Results

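In vitro binding of 40 SPL proteins to naked genomic DNA was mapped in bread wheat, an allohexaploid with A, B and D subgenomes. SPL proteins are plant transcription factors with an SBP domain, which recognises a GTAC core, and members of the family shape flowering and inflorescence architecture in grasses. The title and design of the series name SPL networks and the divergence of the subgenomes. The questions addressed here were how far homoeologous proteins share binding regions and how binding is spread over the subgenomes. The 40 lists held 14250748 peaks in total and the input list held 223198.

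SPL16A had the most peaks, 381844, followed by SPL15B with 381220 and SPL13A with 379676. SPL4A had the fewest, 304235, followed by SPL9D with 317056 and SPL7B with 322136. The mean was 356269 ± 18861 peaks (SD, n = 40 lists). The lists differed more in breadth. SPL4A covered 131 Mb of the genome and SPL15D 437 Mb, while the median peak width ran from 322 bp in SPL4D to 809 bp in SPL15D. The 6 SPL proteins with 2 libraries had a median of 349418 peaks, and the 34 with 1 library a median of 360228 (two-sided permutation test of the difference, p = 0.348). No SPL peak overlapped an input peak, against 1.37% ± 0.26 (SD, n = 40 lists) after random placement (sign-flip permutation p = 1e-05, the smallest possible). Every SPL list was free of such overlaps, so this share does not measure background.

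Peaks were densest on the D subgenome and sparsest on the A subgenome in all 40 lists. The A chromosomes carried 21.8 ± 1.24, the B chromosomes 25.1 ± 1.45 and the D chromosomes 30.02 ± 1.56 peaks per Mb (mean ± SD, n = 40 lists). Density on D was thus 1.38 times that on A and 1.20 times that on B, and density on B was 1.15 times that on A. The input list was far more even, at 14.4 peaks per Mb on A, 14.8 on B and 15.1 on D. The log2 ratio of A to D was -0.46 ± 0.04 (SD, n = 40 lists), that of B to D -0.26 ± 0.04 and that of A to B -0.20 ± 0.04. Each had an adjusted sign-flip permutation p of 1e-05, the smallest possible. In the outer 10% at each chromosome end, a setting added after seeing the data, the ratio of A to B was -0.10 ± 0.06 and lay below 0 in 37 of 40 lists. SPL11B had the lowest ratio of A to D, -0.54, and also of A to B, -0.26. The highest ratio of A to D was -0.36 in SPL4D and the highest of A to B was -0.11 in SPL2A. For B to D, SPL16D had the lowest ratio, -0.34, and SPL6A the highest, -0.18.

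**Figure D1:**
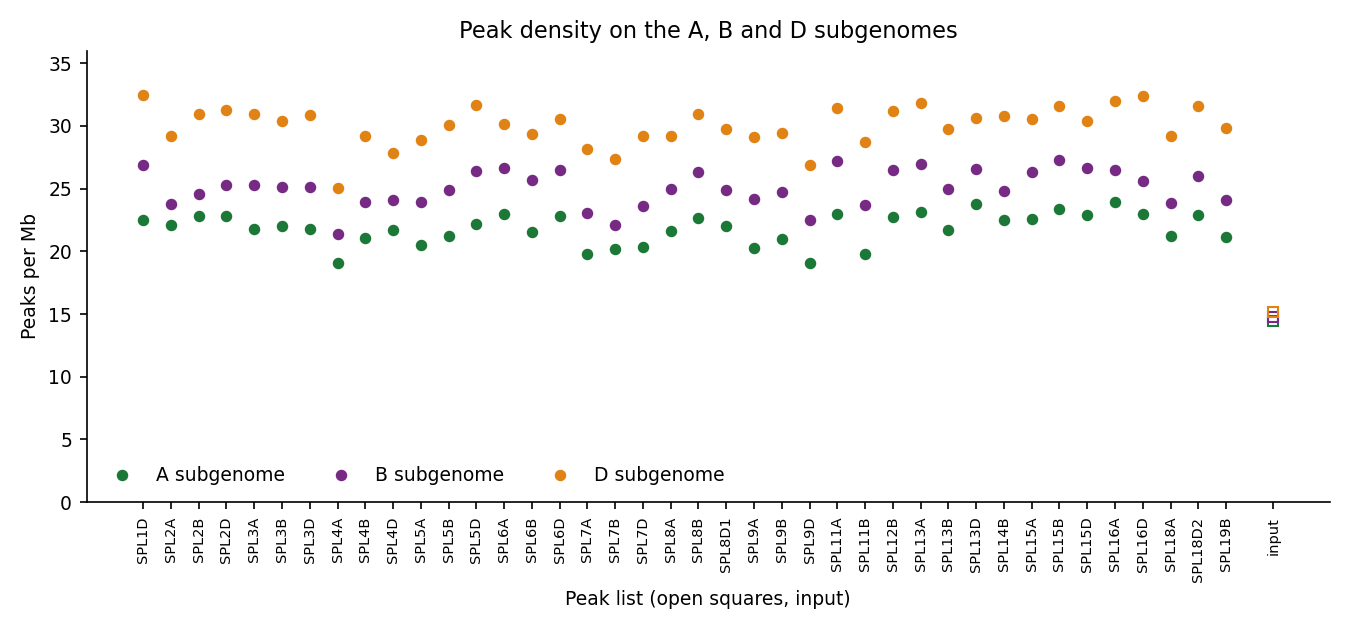
Peaks per Mb on the A, B and D subgenomes (y axis) for each of the 40 SPL lists and the input (x axis), 1 point per list and subgenome. In all 40 SPL lists the D point lies above the B point and the B point above the A point, while the input points lie between 14.4 and 15.1.

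The order held chromosome group by chromosome group. In 7 of 7 groups the D chromosome was denser than its A and B counterparts in all 40 lists, and in 6 of 7 groups the B chromosome was denser than the A chromosome. Group 1 was the exception. Chromosome 1B had 17.6 ± 1.13 peaks per Mb (SD, n = 40 lists), below the 21.2 ± 1.22 of 1A and the 29.7 ± 1.61 of 1D. The deficit lay in the first 241 Mb of 1B, where the lists had 2.44 ± 1.00 peaks per Mb, against 25.7 ± 1.51 on the rest of the chromosome. The first part of 1B kept 4.12% of the density of the rest in SPL13B, the lowest, and 19.2% in SPL15D, the highest. Without this part, 1B was denser than 1A in all 40 lists, as in the other groups. Density on B was then 1.20 times that on A, and density on D was 1.15 times that on B. The input list was lower in the first part of 1B as well, at 2.95 against 15.3 peaks per Mb, with 7.26 per Mb in the first 35 Mb.

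**Figure D2:**
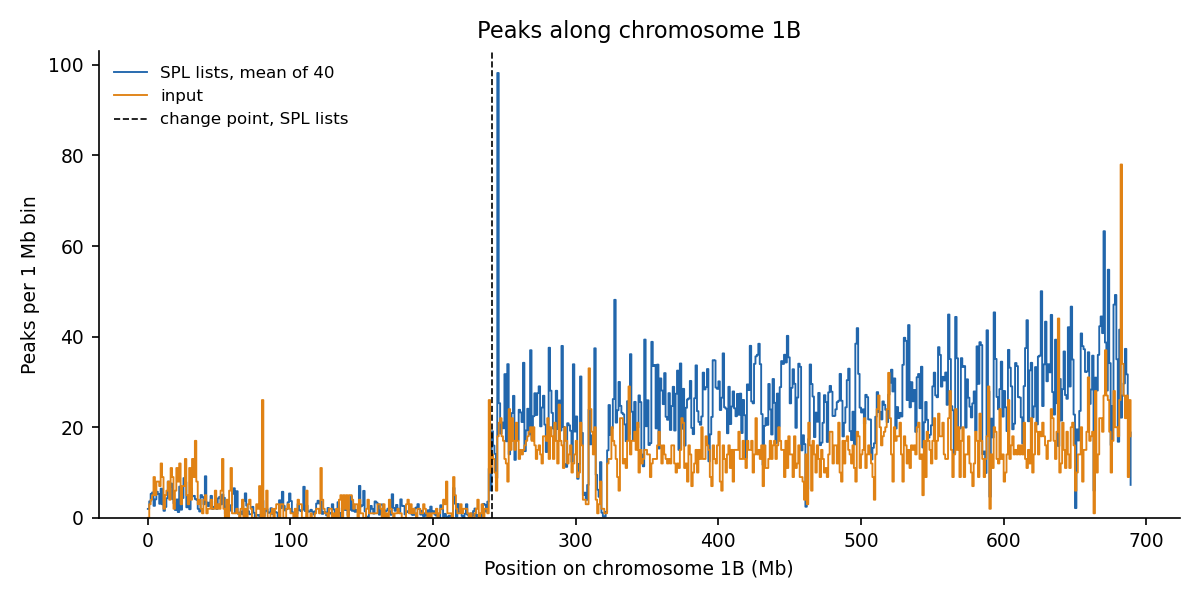
Peaks per 1 Mb bin (y axis) along chromosome 1B (x axis, Mb), as the mean of the 40 SPL lists and for the input list, with the change point of the SPL lists as a dashed line. The SPL mean stays at or below 10.9 per bin up to 241 Mb and averages 25.7 beyond, while the input averages 2.95 before and 15.3 after, with 3 earlier bins at or above 15.3.

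Homoeologous SPL proteins shared more regions than SPL proteins of different numbers. The mean Jaccard index was 0.502 ± 0.108 (SD, n = 33 pairs) for homoeologs and 0.388 ± 0.074 (SD, n = 747 pairs) for other pairs. The difference of 0.115 had a two-sided permutation p of 1e-05, the smallest possible. All pairs lay far above randomly placed peaks, for which the index was 0.018 ± 0.003 (SD, n = 780 pairs). With whole lists shifted it was 0.019 ± 0.007, with a maximum of 0.152. Some lists drew nearly equal distances, the closest 752 bp apart. Such pairs can keep part of their real overlap, so the maximum need not be background. By raw index SPL15, which had the widest peaks, was the most similar set, with a mean of 0.661 and a top value of 0.706 between SPL15A and SPL15D. SPL4, with narrow peaks, was the least similar by raw index, with a mean of 0.295, and SPL4A, SPL4B and SPL4D averaged 0.321 with other numbers. SPL16A and SPL16D had 0.310 with each other and averaged 0.341 with other numbers. Homoeologs exceeded other pairs in 11 of 13 sets. Batches of libraries were not given in the sources used here, so a batch shared by homoeologs cannot be told apart from homoeology. After an additive term for each list was removed from log2 Jaccard, an adjustment added after seeing the data, the order changed. SPL2 (0.55) and SPL6 (0.44) then lay above SPL15 (0.42), while SPL16 (0.08), SPL3 (0.12) and SPL5 (0.18) lay below SPL4 (0.21). The pair of SPL4A and SPL4D, lowest among homoeologs by raw index at 0.286, had a residual of 0.43.

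Similarity also crossed the SPL numbers. SPL8B and SPL13A had an index of 0.696, the second highest of 780 pairs, and the 9 pairs of SPL8 with SPL13 averaged 0.566. SPL8 with SPL12B averaged 0.585 and SPL6 with SPL15 averaged 0.530. Mean residuals were 0.39 for SPL8 with SPL13, 0.22 for SPL8 with SPL12B and 0.24 for SPL6 with SPL15, above the 90th percentile of 0.15 for pairs with different numbers. SPL3 with SPL15 averaged 0.547, but the residual was 0.09, as these lists overlapped widely with most others. At the other end, SPL2A and SPL4D had 0.205, the lowest of all pairs by raw index. Their median widths, 425 and 322 bp, were below the median of 500 bp over lists, and by residual the lowest pair was SPL8B with SPL16D, at -0.26. Of the 36 lists with a homoeolog, 20 had a homoeolog as the nearest list, against 1.69 on average when numbers were permuted (a test added after seeing the data, 20000 permutations, one-sided p = 5e-05, the smallest possible). No difference by the subgenome that encodes the protein was detectable. Pairs with the same letter averaged 0.387 and pairs of different letters 0.388 (two-sided permutation p = 0.892).

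**Figure D3:**
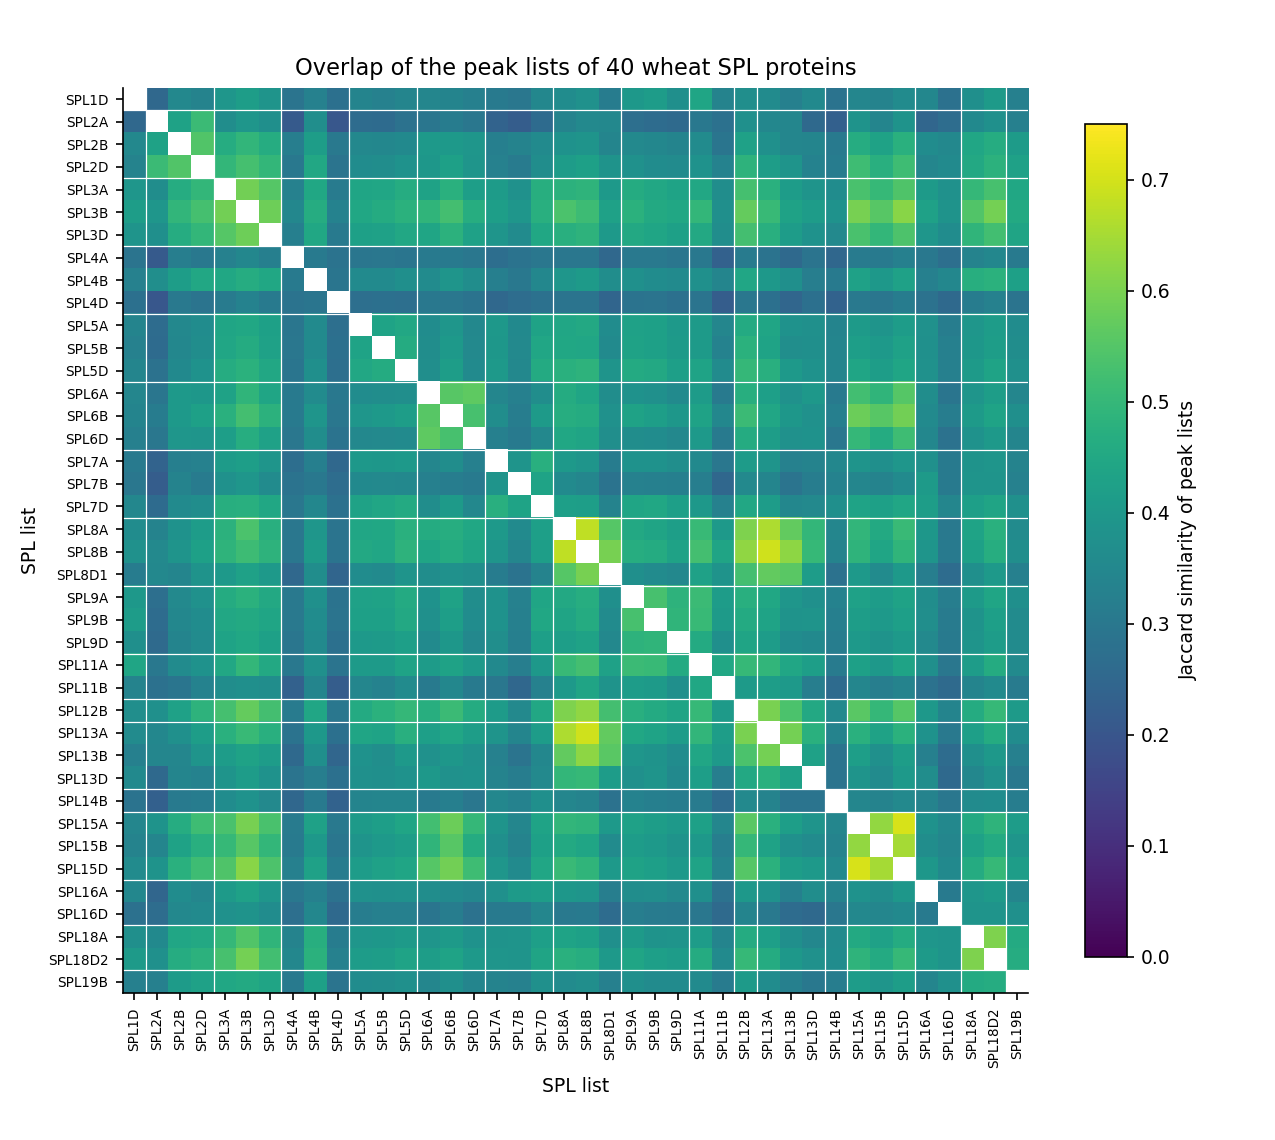
Jaccard index of peak lists (colour, from 0 to 0.75) for each pair of the 40 SPL lists (both axes), with white lines between SPL numbers. The SPL15 block reaches 0.706, the SPL8 and SPL13 lists reach 0.696 across numbers, and SPL2A with SPL4D is lowest at 0.205.

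SPL proteins also differed in how much of their binding lay near chromosome ends, a measure added after seeing the data. The outer 10% at each chromosome end held 27.7% ± 0.69 of the peaks of SPL2 (SD, n = 3 lists) and 27.02% ± 0.17 of those of SPL15 (SD, n = 3 lists). It held 22.1% ± 0.47 for SPL13 (SD, n = 3 lists), 21.2% ± 0.91 for SPL11 (SD, n = 2 lists) and 21.1% for SPL1D, against 24.2% of input peaks. SPL2D was highest of all lists at 28.5% and SPL11B lowest at 20.5%. Differences between SPL numbers accounted for 93.8% of the variance over the 40 lists, against 40.99% on average with permuted numbers (adjusted permutation p = 5e-05 over 5 measures; unadjusted p = 1e-05, the smallest possible).

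**Figure D4:**
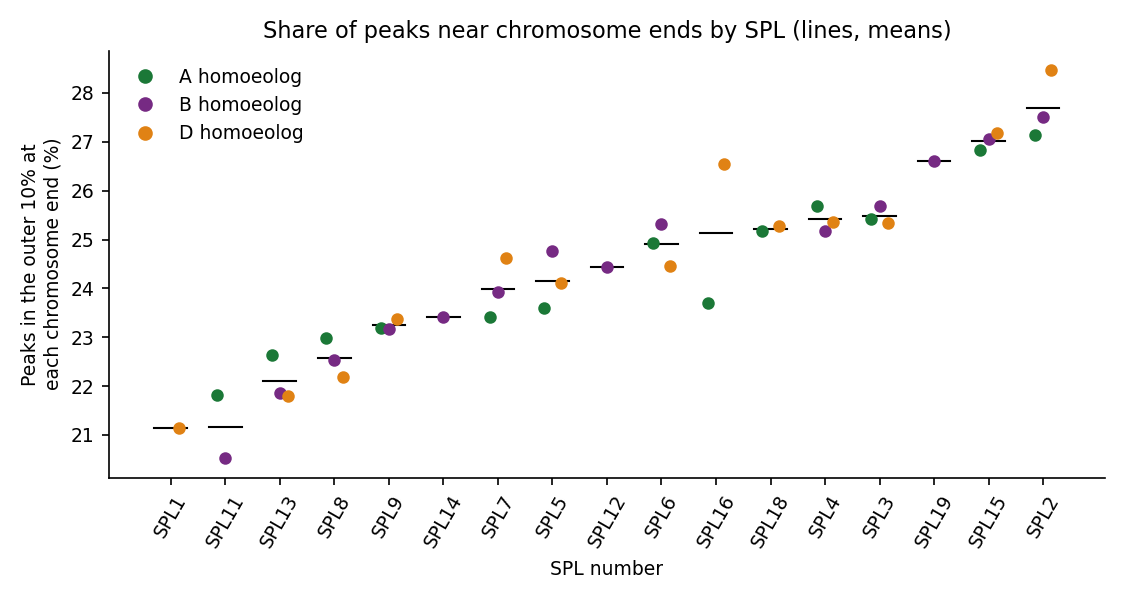
Share of peaks in the outer 10% at each chromosome end (y axis, percent, axis not from 0) for each SPL number (x axis, ordered by mean), with 1 point per list coloured by subgenome letter and lines at the means. The means run from 21.1% for SPL1 to 27.7% for SPL2.

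No preference of SPL proteins for their own subgenome was detectable. The share of peaks on the own subgenome differed from that of the homoeologs there by -0.023 percentage points on average (SD 0.449, n = 36 lists). The two-sided permutation p was 0.803, and 19 of the 36 lists lay above 0. SPL16D had the highest value, 1.06 points, and SPL13D the lowest, -0.92 points. By letter, the means were 0.056 ± 0.443 points for 13 A proteins, -0.140 ± 0.344 for 11 B proteins and -0.002 ± 0.545 for 12 D proteins (SD over lists).

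Regions bound by 1 SPL were the most frequent class, at 39.7% of regions. That share was below the 56.1% after random placement and the 57.4% with lists shifted. Merged regions bound by all 40 SPL proteins outnumbered those of 34 of the 38 intermediate classes, but by base pairs this order did not hold. The 40 lists merged into 1367552 regions, of which 542248 had a peak of 1 SPL and 39056 had peaks of all 40. The smallest class had 8621 regions, at 29 SPL proteins. Random placement gave 6801538 regions, 175 with peaks of at least 20 lists against 248737 observed, and none with more than 29. Shifting each list as a whole by 200000 to 1000000 bp gave 1434 regions with at least 20 lists and 1 with all 40; some lists drew nearly equal distances, the closest 752 bp apart. The counts depended on how a region was drawn: with 200 bp around peak centres, 859095 regions had 1 SPL and 24064 had all 40. Among base pairs, 321 Mb were covered by 1 list and 8.54 Mb by all 40, less than in 34 of the 38 intermediate classes. Private peaks made up 0.19% of SPL3B and 14.9% of SPL4D, and widely shared peaks made up 65.6% of SPL3B and 48.5% of SPL4D.

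**Figure D5:**
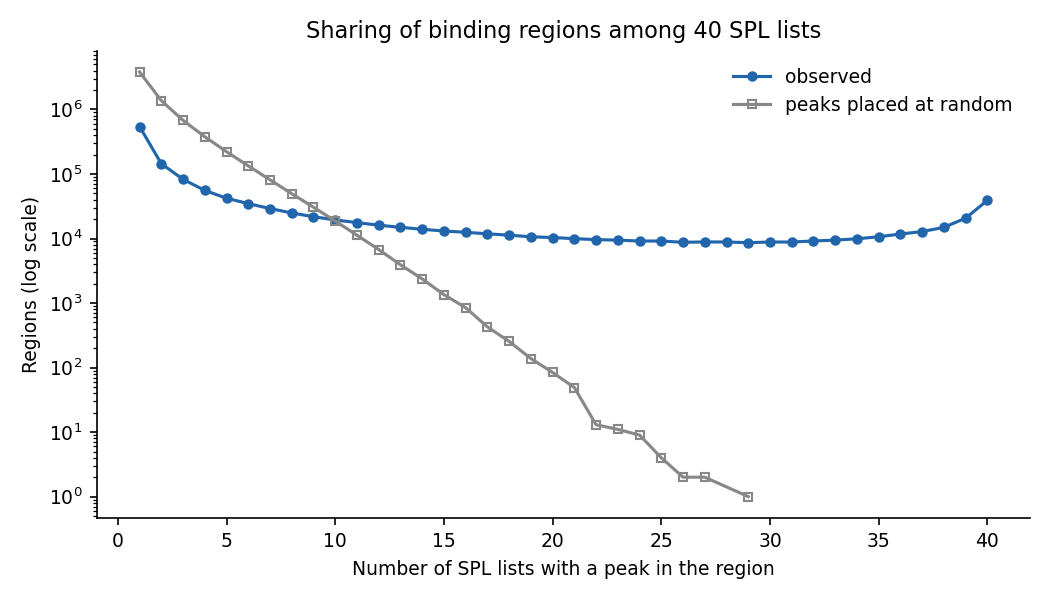
Number of merged regions (y axis, log scale) by the number of SPL lists with a peak in the region (x axis), as observed and after random placement of all peaks. The observed curve falls from 542248 regions at 1 list to 8621 at 29 lists and rises to 39056 at 40 lists.

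The regions bound by all 40 SPL proteins with the widest peaks lay on chromosomes of each subgenome. The first was 5A, 46379198 to 46388848, where the mean width percentile within lists was 99.9. Next came 2D, 526952569 to 526960133, and 4D, 50808286 to 50815385. They were followed by 1B, 406033964 to 406041610, and 7B, 308173539 to 308189438. The 7B region, at 15900 bp with 200 peaks merged, was the longest of the 10. The others were 6B, 618275350 to 618282580, 5B, 691189167 to 691195959, and 2A, 120443143 to 120449641. The last were 1D, 300857064 to 300863700, and 4B, 73638146 to 73646911. Each of the 10 regions merged between 59 and 200 peaks. No library of the tag or beads alone was in the series, so background common to all 40 lists was not measured. Genes in these regions were not analysed here.

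Wide peaks were shared far more often than narrow peaks, and they lay more often on D. Among the widest 25% of peaks, 93.1% ± 7.25 (SD, n = 40 lists) were widely shared, against 25.2% ± 5.42 of the narrowest 25%. The difference of 67.8 percentage points was above 0 in 40 of 40 lists (sign-flip permutation p = 1e-05, the smallest possible). A wide peak meets other peaks more easily. Counting only peaks whose centre lay in a peak of the other list, a measure added after seeing the data, the shares were 82.9% and 19.9%. The widest peaks had 34.4% on D against 32.2% for the narrowest, a difference of 2.16 ± 1.13 points that was above 0 in 38 of 40 lists (adjusted sign-flip permutation p = 1.5e-05). Their shares on A and B were lower, by -0.70 ± 1.29 points (adjusted permutation p = 0.00147) and -1.46 ± 1.02 points (adjusted permutation p = 1.5e-05).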

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

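The tests between SPL numbers and the tests of explanations in this part were chosen after the lists were seen; for the inner 80% of the chromosomes, the bound was set before its value was seen.

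SPL numbers differed in where along the chromosomes they bound, with 93.8% of the variance in the share of peaks near chromosome ends lying between numbers, against 40.99% on average with permuted numbers (adjusted permutation p = 5e-05 over 5 measures; unadjusted p = 1e-05, the smallest possible). SPL16 was a set whose members stood apart, with 23.7% in SPL16A and 26.6% in SPL16D. The permutation tests took the 40 lists of 17 numbers as exchangeable, and 4 numbers had only 1 list. Batches and read depth were not given in the sources used here, so a batch shared by lists of 1 number stays open.

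With permuted numbers the share of variance between SPL numbers averaged between 40.97% and 41.03% for the measures of this paragraph. It was 80.7% for the log2 ratio of B to A density, from 0.12 in SPL2 to 0.26 in SPL1 (adjusted permutation p = 0.000475). For the log2 ratio of D to A it was 62.7%, from 0.41 in SPL4 to 0.53 in SPL1 (adjusted permutation p = 0.0248). For the share of private peaks it was 80.9%, from 0.496% in SPL12 to 14.5% in SPL14 (adjusted permutation p = 0.0012). For median peak width it was 71.9%, from 350 bp in SPL14 to 744 bp in SPL15 (adjusted permutation p = 0.00296). Private share and width are not separate measures, since wider peaks overlap other lists more easily, and SPL14 lay at an end of both ranges. SPL1, SPL12 and SPL14 had 1 list each, so these extremes have no homoeolog to set them against.

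The first 241 Mb of chromosome 1B held few peaks in all 40 SPL lists, at 9.46% ± 3.70 (SD, n = 40 lists) of the density of the rest of 1B. Weaker binding by SPL proteins cannot be the whole cause, since the input list also had 19.2% of its density on the rest, though in the first 35 Mb the input had 47.3% and the SPL lists 17.2%, a gap that stays open. The change points of the pooled SPL lists and of the input lay 2 Mb apart, at 241 and 239 Mb. Those of single SPL lists ran from 239 to 245 Mb. Given such close positions, a candidate explanation of the deficit is that the reference sequence of this arm is missing from the DNA used. AiKang58 is known to carry the short arm of rye chromosome 1R in place of that of 1B, which would have this effect, but no rye sequence was used here. Reads that could not be placed on this arm cannot be told apart from a missing arm by these lists; low segments elsewhere were at most 12 Mb long, on 6B.

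The excess of peaks on D over A, a mean log2 ratio of 0.46, was weighed against 3 technical explanations. The input list had a log2 ratio of 0.0693, far under the lowest SPL value of 0.36, which argues against the density of input peaks. The lowest log2 ratio in the inner 80% of the chromosomes was 0.35, which argues against the chromosome ends as the only cause. Widely shared peaks had a log2 ratio higher by 0.22 than private peaks (SD 0.15, higher in 39 of 40 lists, sign-flip permutation p = 1e-05, the smallest possible), but this does not decide on one factor for all peaks, since peaks on denser D are less easily private and private peaks lay nearer input peaks. One such factor therefore stays open, as do the numbers of binding motifs, genes and repeats per Mb on each subgenome, as the sequence was not used here, and no biological explanation was tested.

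SPL8 and SPL13 shared more regions than most homoeologous sets did. Wide peaks overlap more often, but after an additive term per list the median residual of the 9 pairs lay at percentile 99.3 of pairs with different numbers. A high share of widths in multiples of 25 bp was not enough for such residuals. SPL2 had at least 96.0% of such widths, and its median residual with SPL8 and SPL13 lay at percentile 18.3. SPL1D, at 97.5%, had mean residuals of -0.086 with SPL8 and -0.010 with SPL13. The SPL11 lists, at 89.1% and 89.7%, averaged 0.146 and 0.133, so a part played by the processing was not excluded. A candidate explanation is a shared sequence preference of SPL8 and SPL13, which was not tested. Batches of libraries were not given in the sources used here and also stay open.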

How the results depend on the processing

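Of 84 alternative values, 78 kept both the direction and the side of the threshold. A further 2 passed 0.05 only in the alternative, and 4 counts of regions moved by more than 1.5 times. Some of the 78 could not have differed. The ratio of A to D without the first part of 1B uses no B chromosome. No SPL list overlapped input peaks, so the reciprocal overlap of 50% had to lie below random placement. The alternatives based on width, base pairs, centres, list terms, chromosome zones and the start of 1B, and all settings for private peaks, were chosen after seeing the data, except the 200 bp windows for shared regions. The homoeolog difference stayed between 0.106 and 0.124 when each SPL number was left out in turn. Regions with 1 SPL numbered 859095 with 200 bp around peak centres and 175942 with the widest 50% of each list, and regions with all 40 numbered 24064 and 17467. The second setting uses fewer peaks by construction; for the first, the cause was not tested. The difference between widely shared and private peaks in the share on B passed 0.05 at 0.532 points by peak centres and at 0.630 points without the first part of 1B, against 0.453 points before; the cause was not tested.

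No paired analysis was possible because the 6 SPL proteins with numbered libraries had 1 pooled list each. The alternatives that needed a score (strongest 50%, equal numbers of strongest peaks), a gene annotation or a genome were not run. Leaving out peaks that overlap input peaks was not run, because no SPL list held such peaks. Read depth per list is unknown, so its effect on the number and width of peaks was not tested.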

Other observations

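The values in this part were chosen after the lists were seen. Private and widely shared peaks of the same SPL differed in several measures. Widely shared peaks had a median width of 761.6 ± 233 bp and private peaks of 257 ± 16.5 bp (mean ± SD over 40 lists), which is partly built in, since wider peaks overlap other lists more easily. No difference was detectable in the share in the outer 10% at chromosome ends, 24.4% ± 0.85 for widely shared and 23.03% ± 5.44 for private peaks (sign-flip permutation p = 0.109, higher for widely shared peaks in 29 of 40 lists). A larger share of private peaks lay within 1 kb of an input peak, 6.21% ± 2.15 against 2.86% ± 0.27, and the direction held in 40 of 40 lists (sign-flip permutation p = 1e-05, the smallest possible). This difference can be partly built in as well. No list held a peak that overlapped an input peak, and close to an input peak a wide peak overlaps it more easily than a narrow one. Of private peaks 31.7% ± 2.05 lay on D, against 33.8% ± 0.31 of widely shared peaks, and 32.3% ± 1.76 against 29.7% ± 0.25 lay on A (SD, n = 40 lists; adjusted sign-flip permutation p = 1.5e-05 for each).

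The D share of merged regions, for which no test was run, was 31.4% among regions of 1 SPL, 36.6% among regions of 39 and 33.5% among regions of all 40. Outside 1B, low segments were found on 2B (124 to 128 Mb), 3A (2 to 6 Mb) and 6B (262 to 274 Mb and 426 to 430 Mb). In these the SPL lists and the input each had under 25% of the chromosome's median density.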
